A study of Mus musculus with 4 samples.

How the data were processed

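The study compared mouse mucosal mast cells stimulated with interleukin 18 (IL-18) against unstimulated cells of the same kind on 4 arrays of 2 colours each. Per the labels, each array is 1 of 4 biological replicates, the stimulated RNA was labelled with Cy5 and its own unstimulated control with Cy3. Total RNA was purified on columns with DNase digestion, checked on a Bioanalyzer, and turned into labelled cRNA, per the labels' protocols. Every array has the same dye orientation. A difference between the dyes that is specific to a probe therefore cannot be separated from the effect of IL-18 by the design.

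The intensity values used here are the mean brightness of each spot and the median brightness of its local background in both channels, as the authors' scanner software, Agilent Feature Extraction 9.1, gave them per the file headers. These intensities had not been corrected for background or dye. The same deposited files also hold processed intensities and a log10 ratio of Cy5 over Cy3 for each spot, which the authors' software made by background subtraction with spatial detrending and a linear and lowess dye normalization, per the file headers. A deposited table of the whole series holds log10 ratios too. Its values differed from the scanner files' log10 ratios by at most 0.00496 in any row of any array, its column medians were 0 on all 4 arrays, and it runs in the same direction, Cy5 over Cy3. Both log10 ratios were used only as alternatives. Flags of the software (well above background, saturated, outlier) were used as given in the deposited files.

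Background was corrected with limma's normexp method and an offset of 50 over all spots. Log2 ratios of Cy5 over Cy3 were then normalized within each array by loess, with control spots and spots flagged as outliers given no weight. Control spots were left out afterwards and flagged spots set to missing, and the spots of 1 probe were averaged. A probe was tested if it was well above background in the same channel on at least 3 of the 4 arrays and had at least 3 values. The mean log2 ratio of each probe was tested against 0 with limma 3.58.1 (lmFit with an intercept, then eBayes) in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over all tested probes and a threshold of 0.05. Because the ratio on an array is the difference within 1 pair, this is the paired test. All adjusted p-values of genes come from limma. An exact sign-flip test of 4 arrays cannot go below p = 0.125, so no such test could pass the threshold and none is reported for single genes.

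A gene was represented by its brightest tested probe. Gene names are those of the array's design, replaced by the current symbol where the spot's accession was found in a RefSeq gene table of assembly GRCm38.p6. This held for 24913 of the 43379 gene spots and for 11107 of the 16970 tested genes, and the array's own name was kept for the rest, so that probes of 1 gene can stand under an older and a newer name. The files name no genome build, and no coordinates are given. Probe sequences were not used here.

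The gene lists were fixed before the data were examined. There are 28 of them: IL-18 receptor and signalling, NF-kB, chemokines, cytokines and growth factors, immediate-early genes, costimulatory and TNF superfamily genes, mast cell proteases, mast cell receptors, the mucosal programme, eicosanoid synthesis, JAK-STAT signalling and its inhibitors, interferon-stimulated genes, apoptosis, cell cycle, unfolded protein response, glycolysis, sterol synthesis, adhesion, oxidative stress, housekeeping genes, and markers of 8 kinds of other cells. Each list was tested with limma's camera on the moderated statistics, with a preset correlation between genes of 0.01, two-sided, and Benjamini-Hochberg adjustment over the 28 lists. Camera with a correlation estimated from the 4 arrays and limma's fry were run beside it. Camera compares a list with the other genes, while fry tests the list's own log2 ratios against 0, so their calls answer different questions. For camera with an estimated correlation, 4 arrays leave few degrees of freedom, so its p-values can be large also where the estimated correlation is low. Members are counted past the threshold over all tested probes and also adjusted over the list alone.

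The genes named in the text follow a rule fixed at the same time: the 12 largest rises and 8 largest falls past the threshold with the same sign on all 4 arrays and a plain symbol; up to 3 members past the threshold of each list, or the 1 with the largest log2 ratio where none passed; and, always, Ccl1, Ccl2, Ccl3, Il6, Il13, Il4, Tnf, Il18r1, Il1rl1, Mcpt1, Mcpt2, Kit, Fcer1a, Nfkbia and Tnfaip3. A few genes that this rule picks are not reported here as single genes. Other members are named where a count is 5 or fewer, and those were chosen after their values were seen.

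These steps were tested on simulated arrays with the real intensities, dye trends and replicate spread. Of 50 probes changed by 0.25 on the log2 scale, among the 24104 probes fitted, 10% were recovered at the threshold. The shares were 74% of 50 at 0.5, 86% of 50 at 1, and 98% of 50 at 2, and 6 of 23879 unchanged probes were called. The median estimate was 0.780 to 0.914 of the simulated change. In the same simulation a list shifted by 0.5 was called and none (0) of the other lists was. The simulated noise was independent between spots, with no correlation between genes and no dye effects of single probes. These results therefore do not cover false calls of probes or lists from such effects.

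Alternatives were the median of a gene's probes, the software's log ratio, the series table, no background subtraction, a normexp offset of 0, median centring in place of loess, scale normalization between arrays, no filter on dim probes, both channels above background on all 4 arrays, saturated spots left out, flagged spots kept, the channels fitted separately without the pairing, eBayes with trend and robust settings, slide as a random block, each replicate left out, a threshold of 0.01 and a 2-fold minimum. Arrays of replicates 1 and 2 share 1 slide and those of replicates 3 and 4 another. The number of arrays limits the precision. Across tested genes the median SD of the log2 ratio over arrays was 0.0992.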

Results

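Gene expression was measured in mouse mucosal mast cells that had been differentiated in vitro and then stimulated with IL-18, an inflammatory cytokine of the IL-1 family, or left unstimulated. Mucosal mast cells are the mast cells typical of epithelia such as the gut lining, and the chymase genes Mcpt1 and Mcpt2 are their usual markers. Each of 4 biological replicates was 1 array on which the stimulated sample (Cy5) and its own unstimulated control (Cy3) were hybridised together. The comparison asks which transcripts differ between stimulated and unstimulated cells of the same replicate. Dose and duration of the stimulation are not given in the sources used here. The dyes were not exchanged on any array, so each ratio holds the effect of IL-18 together with any difference between the dyes.

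Every array carried 43379 gene spots and 1639 control spots. Between 49.9% and 54.0% of the gene spots were well above background in the unstimulated channel, and between 57.9% and 62.7% in the stimulated channel. No gene spot (0) was saturated on any array, and 12 to 29 were flagged as outliers. Across the 24104 tested probes, which are not independent of one another, the log2 ratios of different arrays correlated with Pearson's r from 0.619 (replicates 1 and 4) to 0.906 (replicates 2 and 3). The arrays that shared a slide had an r of 0.761 (replicates 1 and 2) and 0.846 (replicates 3 and 4).

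Chemokine genes, a cytokine gene and genes of NF-kB inhibitors were among the largest rises in the stimulated channel. The largest was that of Ccl1, a chemokine gene, with a log2 ratio of 2.28 ± 0.37 (SD, n = 4), or 4.86-fold. Nfkbia, which encodes the NF-kB inhibitor IκBα, rose by 2.16 ± 0.17 (4.48-fold). Il1b, the gene of interleukin 1β, rose by 2.15 ± 0.20 (4.43-fold), the chemokine gene Ccl3 by 1.83 ± 0.21 (3.55-fold) and Nfkbiz, which encodes a nuclear IκB protein, by 1.75 ± 0.09 (3.37-fold). All of these were higher on 4 of 4 arrays, and their adjusted p-values in limma lay between 1.75e-04 and 6.44e-04.

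Others among the 12 largest rises were Irg1 (now Acod1), the enzyme that makes itaconate, at 1.60 ± 0.54, Traf1, an adaptor of TNF receptors, at 1.55 ± 0.35, and Zc3h12a, a ribonuclease that degrades inflammatory mRNAs, at 1.49 ± 0.49 (SD, n = 4). Both tested probes of Irg1 rose, the other by 1.53. With the scanner software's own log ratio the values of Irg1 and Zc3h12a were larger, 2.90 and 2.34. Fos, a subunit of the AP-1 transcription factor, rose by 1.28 ± 0.41 and Nr4a1, an orphan nuclear receptor induced early after many stimuli, by 1.25 ± 0.30. The ribosomal protein genes Rpl41 and Rpl12 stood among the same 12, at 1.45 ± 0.22 and 1.35 ± 0.16. Each of these 7 genes was higher on 4 of 4 arrays.

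**Figure D1:**
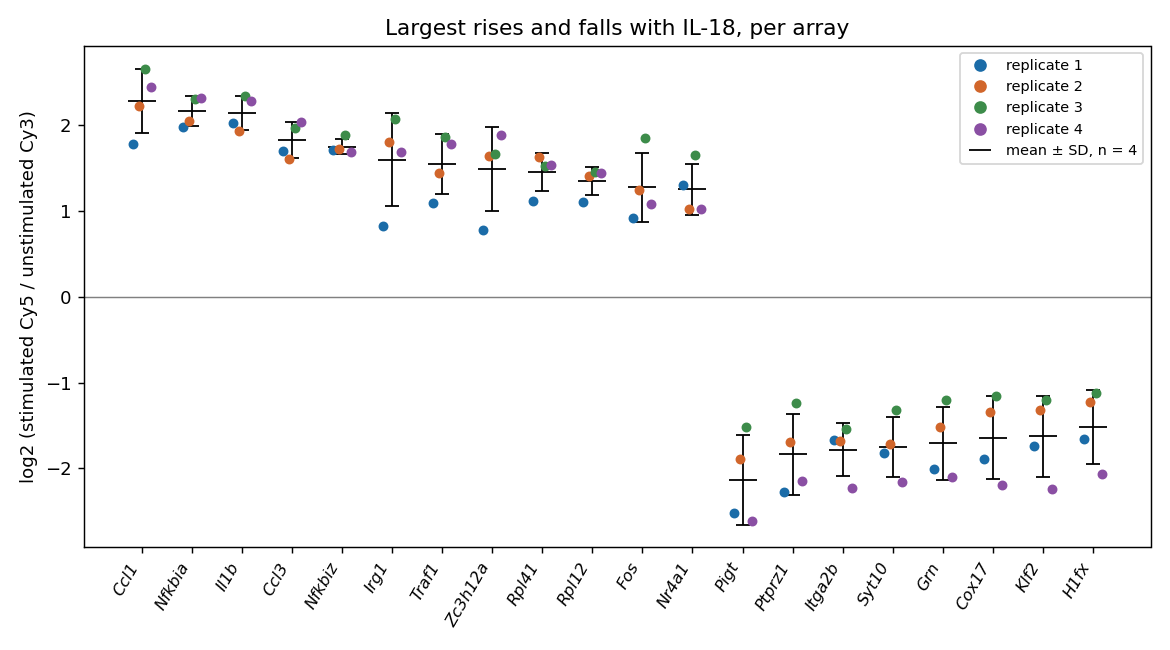
Log2 ratio of stimulated (Cy5) over unstimulated (Cy3) cells on the vertical axis for the 12 genes with the largest rise and the 8 with the largest fall; coloured points are the 4 replicates, bars the mean and SD. Every point of the rising genes lies above 0 and every point of the falling genes below 0, with replicate 3 nearest to 0 for each of the falling genes.

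The largest falls were those of Pigt (−2.13 ± 0.52), Ptprz1 (−1.84 ± 0.47), Itga2b (−1.78 ± 0.31), Syt10 (−1.75 ± 0.35), Grn (−1.71 ± 0.42), Cox17 (−1.64 ± 0.48), Klf2 (−1.62 ± 0.47) and H1fx (−1.52 ± 0.43; SD, n = 4). Pigt encodes a subunit of the enzyme that attaches GPI anchors, Grn the growth factor progranulin, Cox17 a copper chaperone of cytochrome c oxidase, and Klf2 a transcription factor. All 8 were lower on 4 of 4 arrays, with adjusted p-values from 6.65e-04 to 0.00176. Bright other probes of 3 of these genes did not show falls of this size: that of Cox17 rose by 0.43, that of Klf2 by 0.29, and that of Grn read −0.40. The other probes of Pigt and Ptprz1 read −0.23 and −0.24, and a probe under H1f10, the newer name of H1fx, read 0.01. These last 3 were dim, with a mean log2 intensity of 7.63, 7.80 and 7.33 against a median of 9.17 over genes. The called probes of Pigt, Ptprz1 and H1fx were far brighter, at 16.15, 17.49 and 14.52. Whether the bright and the dim probe of such a gene measure the same transcript was not tested. The offset of 50 pulls ratios of dim probes toward 0, but whether it takes falls of this size to these values was not tested. Top2a and Irf7, with intensities of 7.50 and 7.69, read −0.37 and −0.51 with the offset. With the scanner software's log ratio they read −0.88 and −1.05. Itga2b and Syt10 had 1 tested probe each. With median centring in place of loess the falls of Ptprz1, Grn, Cox17, Klf2 and H1fx no longer passed the threshold (log2 ratios −0.19, −0.10, −0.20, −0.27 and −0.28), and those of Pigt, Itga2b and Syt10 shrank to −0.66, −0.76 and −0.85.

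In all, 3346 of 16970 tested genes passed the threshold as higher in stimulated cells and 2320 as lower, which is 33.4% of the tested genes. Most of these differences were small. The median absolute log2 ratio of the called genes was 0.28, and 33 genes rose and 55 fell at least 2-fold. At an unadjusted p under 0.05, 7848 genes passed. Of the 16930 genes with 4 values, 58.2% had the same sign on every array, where chance gives 12.5%. Different probes of 1 gene often differed: of 5223 genes with more than 1 tested probe, 289 had every probe higher, 360 every probe lower, and 286 had probes past the threshold in both directions. Across genes, which are not independent replicates, the log2 ratios of the brightest and the next probe correlated with r = 0.429, and with r = 0.507 over the 2025 genes with both probes at or above the median intensity. The split of the calls rests on the removal by loess of a trend of the ratio with brightness, whose source, dye or transcript, was not tested. Over gene spots the mean signal per array was 2968 to 3737 in Cy5 and 1156 to 1385 in Cy3. The median signals were alike, at 93.2 to 104.6 and 90.2 to 102.4, so centring on the median leaves this trend in. With median centring instead, the median log2 ratio of the probes tested moved from 0.02 to 0.43 and 10701 genes were called higher and 77 lower, so that 99.3% of the calls were higher instead of 59.1%. Median centring raised the log2 ratio of each of the 94 named genes, by 0.13 to 1.65 with a median of 0.80, so the fold values of rises are larger and those of falls smaller or reversed under it. The directions given here are therefore relative to the loess trend with brightness. Bright genes still lay somewhat above it. Random lists matched on brightness to ribosomal protein genes and mast cell protease genes had medians of 0.18 and 0.11. Without replicate 2 the counts fell to 1039 higher and 569 lower, and without replicate 3 to 1275 and 804.

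NF-kB is the transcription factor on which signalling from the IL-18 receptor converges. Of 25 measured genes of this pathway and its feedback, 19 rose, 1 fell and 5 did not pass the threshold; adjusted over the list alone, 20 rose and 1 fell. The 3 largest were Nfkbia, Nfkbiz and Traf1, given above. Only 1 of the 3 risen genes with more than 1 tested probe rose at every probe. Tnfaip3, which encodes the deubiquitinase A20 that restrains the pathway, rose by 0.76 ± 0.08 (SD, n = 4). Rela, a subunit of NF-kB itself, was the member that fell, by 0.21. The genes of the list were shifted by 0.57 relative to all others (camera, adjusted p = 3.72e-23; adjusted p = 0.604 with an estimated correlation).

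Chemokine genes, whose products attract leukocytes, were measured for 14 members, of which 10 rose and none (0) fell; adjusted over the list alone, 11 rose. Besides Ccl1 and Ccl3, Ccl5 rose by 0.85 ± 0.12 (SD, n = 4), with its second probe at 0.89, and Ccl2 by 0.45 ± 0.06 (1.37-fold), each on 4 of 4 arrays. Among the 3 risen chemokine genes with more than 1 tested probe, Ccl5 alone rose at every probe. The shift of the list was 0.55 (camera, adjusted p = 1.12e-09; adjusted p = 0.604 with an estimated correlation). In the list of cytokines and growth factors 13 of 22 measured genes rose and none (0) fell, 15 adjusted over the list alone. Here 3 of the 4 risen genes with more than 1 tested probe rose at every probe. Tnf rose by 0.86 ± 0.16 (1.81-fold), Ltb, which encodes lymphotoxin β, by 0.75 ± 0.26, Il6 by 0.64 ± 0.17 (1.56-fold) and the type 2 cytokine gene Il4 by 0.59 ± 0.08. Il13, the other type 2 cytokine gene named in advance, rose by 0.18 ± 0.10 (adjusted p = 0.0399 in limma). With median centring Tnf read 1.59, Ltb 1.73, Il6 1.95, Il4 1.33 and Ccl2 1.62. Il13 read 0.33 with the software's log ratio and did not pass without replicate 2, 3 or 4. The list was shifted by 0.34 (camera, adjusted p = 2.19e-07; adjusted p = 0.604 with an estimated correlation).

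Immediate-early genes are transcribed within minutes of many stimuli without new protein synthesis. Of 27 measured, 18 rose and 3 fell (Klf2, Jund and Nr4a2); adjusted over the list alone, 18 rose and 4 fell. Fos and Nr4a1 were the largest rises that share the list with Klf2, the largest fall, whose other probe rose. At every tested probe, 2 of the 5 risen genes with more than 1 probe rose. The list was shifted by 0.30 (camera, adjusted p = 2.19e-06; adjusted p = 0.604 with an estimated correlation). Costimulatory and TNF superfamily genes were higher in 11 of 22 cases and lower in 4 (Tnfsf8, Tnfsf14, Tnfrsf18 and Cd44), with 12 and 4 adjusted over the list alone. Of the 2 risen genes with more than 1 tested probe none (0) rose at every probe. Fas, the death receptor gene, rose by 1.21 ± 0.33 (2.31-fold; SD, n = 4), Cd69, an early activation antigen of leukocytes, by 1.14 ± 0.13 (2.20-fold), and Tnfsf4, which encodes OX40 ligand, by 0.68 ± 0.27. With the scanner software's log ratio Fas read 2.12 and Tnfsf4 1.24. The shift of this list was 0.21 (camera, adjusted p = 0.00508; adjusted p = 0.604 with an estimated correlation).

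**Figure D2:**
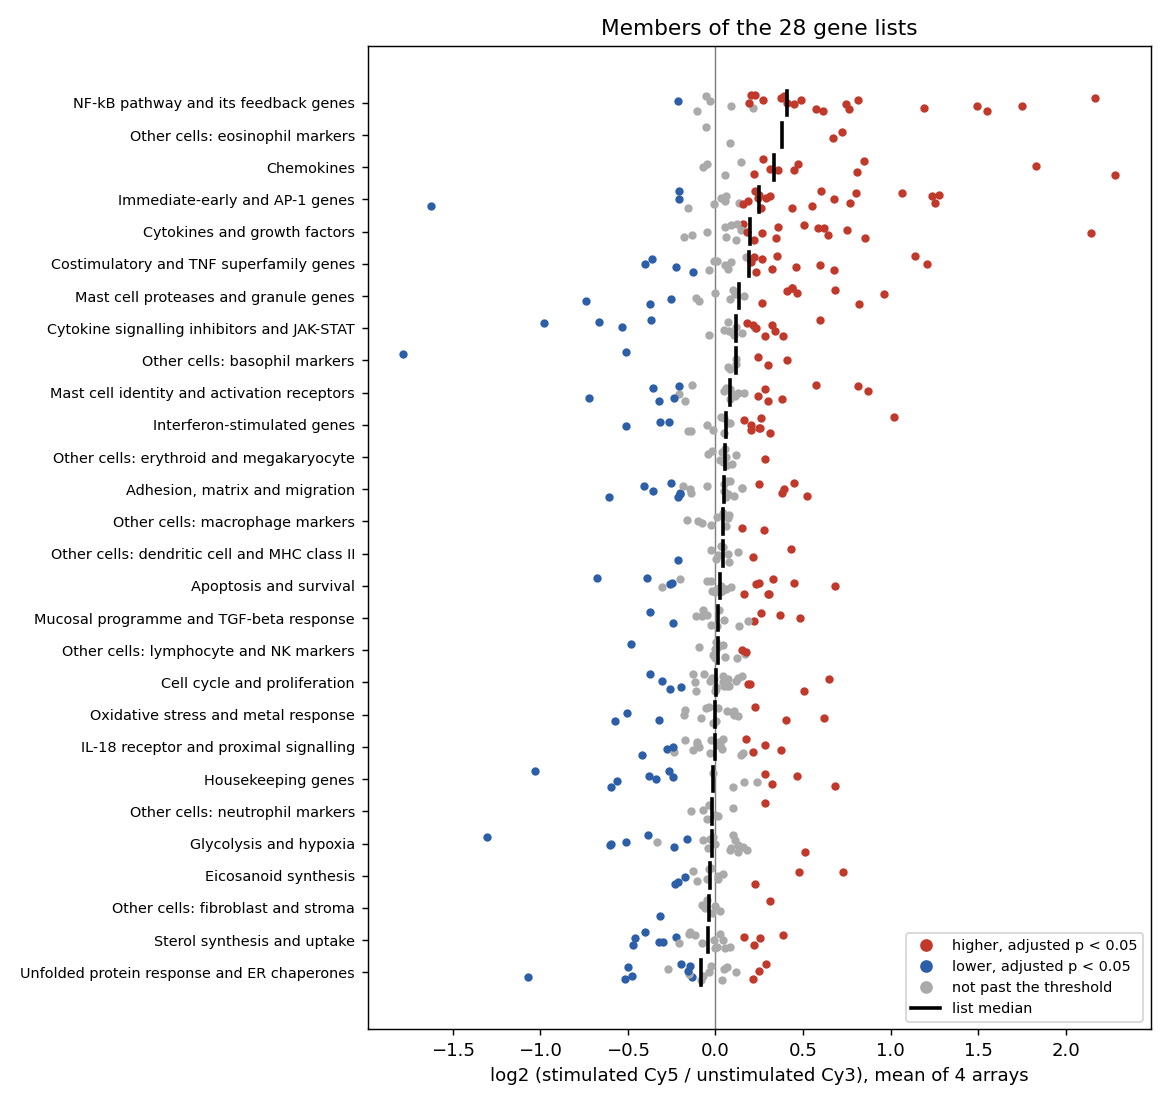
Mean log2 ratio of stimulated (Cy5) over unstimulated (Cy3) cells over 4 arrays on the horizontal axis, 1 point per measured member of the 28 gene lists (vertical axis), coloured by its call; black ticks are list medians, and vertical offsets of points carry no meaning. The NF-kB list has a median of 0.41 and the chemokine list 0.33, while the housekeeping list lies at −0.01, a value, relative to the loess trend with brightness, that turned positive with median centring.

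Mast cell genes moved in both directions. Of 18 measured protease and granule genes, 8 rose and 3 fell (Tpsb2, Ctsg and Ndst2), the same numbers adjusted over the list alone, and the list did not pass the threshold (shift 0.17, camera, adjusted p = 0.256). Its median of 0.14 lay above 62.5% of 10000 random lists matched on brightness, whose median was 0.11. Gzmc, which encodes a granzyme, rose by 0.96 ± 0.16 (1.95-fold; SD, n = 4). Cma1, a chymase gene, rose by 0.82 ± 0.17, and its other probe by 0.34. Mcpt1, the chymase gene of mucosal mast cells, rose by 0.69 ± 0.25 (1.61-fold). Mcpt2 read 0.16 ± 0.17, with 3 of 4 arrays above 0, and did not pass (adjusted p = 0.116). It passed in 4 of 21 alternatives, among them without replicate 1, at 0.24, and with median centring, at 1.69. Tpsb2, the gene of mast cell tryptase, fell by 0.74 (SD 0.07) but read 0.47 with median centring. With the scanner software's log ratio Mcpt1 read 0.34, Cma1 0.44 and Mcpt2 −0.14, and with median centring Mcpt1 read 2.23 and Cma1 2.39.

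Among 23 measured receptors and regulators of mast cells 7 rose and 5 fell (Csf2rb, Mitf, Lat, Lat2 and Btk), or 8 and 6 adjusted over the list alone, without a call for the list (shift 0.06, adjusted p = 0.421). Cd63, a granule membrane protein that reaches the surface on degranulation, rose by 0.87 ± 0.12 (SD, n = 4), and Fcer1a, the IgE-binding chain of the high-affinity IgE receptor, by 0.81 ± 0.36. With the software's log ratio these values were 0.44 and 0.40, and with median centring 2.48 and 2.40. Csf2rb, the shared β chain of the IL-3, IL-5 and GM-CSF receptors, fell by 0.72 (SD 0.18), but a brighter probe that carries its older name, Csf2rb1, rose by 0.55 ± 0.19, so its direction differs between probes. Kit, the receptor for stem cell factor, read 0.05 ± 0.16 with 2 of 4 arrays on either side of 0 (adjusted p = 0.591), and passed with median centring, at 1.41. Csf2rb read −0.28 and Kit −0.12 with the software's log ratio, and Csf2rb turned to 0.078 with median centring. Both mast cell lists passed as higher with median centring, with shifts of 0.85 and 0.61, but had shifts of −0.036 and −0.042 with the software's log ratio. The protease list also passed with eBayes with trend and robust settings (adjusted p = 0.0235) and the receptor list with fry (0.0404).

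**Figure D3:**
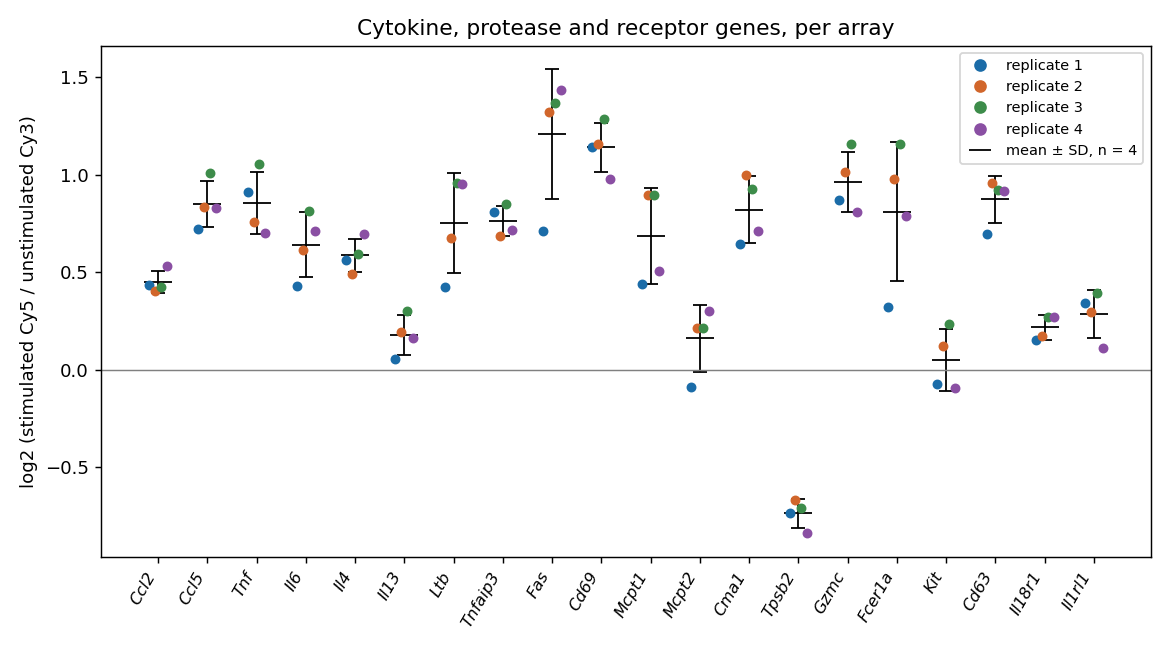
Log2 ratio of stimulated (Cy5) over unstimulated (Cy3) cells on the vertical axis for cytokine, protease and receptor genes; coloured points are the 4 replicates, bars the mean and SD. Tpsb2 lies below 0 on all arrays (mean −0.74, positive with median centring), Kit and Mcpt2 straddle 0, and the other genes shown have all 4 points above 0.

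The genes of the IL-18 receptor and its proximal signalling moved little. Of 22 measured, 4 rose (Ikbkg, Il18bp, Il18r1 and Il18) and 3 fell (Map2k3, Irak4 and Tab1), the same numbers adjusted over the list alone, and the list did not pass (shift −0.03, adjusted p = 0.924). Ikbkg, which encodes NEMO, rose by 0.38 ± 0.13 (SD, n = 4), with 4 probes between 0.06 and 0.38, and Il18bp, the secreted decoy of IL-18, by 0.28 ± 0.08. Il18r1, the IL-18 binding chain of the receptor, rose by 0.22 ± 0.06 (1.16-fold; adjusted p = 0.0138), or by 0.34 with the software's log ratio, and did not pass without replicate 2 (0.23) or 3 (0.20). Il1rl1, the receptor for IL-33, rose by 0.29 ± 0.12 but read −0.08 with the software's log ratio, and did not pass without replicate 2 (0.28) or 3 (0.25). Map2k3 fell by 0.42 (SD 0.26), read 0.50 with median centring, and did not pass without replicate 2 (−0.44) or 3 (−0.45).

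The mucosal and TGF-β response list had 4 of 16 measured genes higher (among them Id2, Skil and Id3) and 2 lower (Pmepa1 and Itgb7), or 5 and 2 adjusted over the list alone (shift 0.03, adjusted p = 0.991, while fry called it higher at 0.0266). Id2, an inhibitor of basic helix-loop-helix transcription factors, read 0.37 ± 0.15 and Pmepa1 −0.37 ± 0.22 (SD, n = 4). Pmepa1 read −0.64 with the software's log ratio, and lost its call with median centring (−0.11) and without replicate 2 (−0.34) or 3 (−0.38), and Id2 without replicate 2 (0.33). In eicosanoid synthesis 3 of 14 rose (Ptgs2, Alox5ap and Alox5) and 3 fell (Ptgs1, Ptges2 and Ptgis), as also adjusted over the list alone (camera, adjusted p = 0.963, with a shift of 0.02, a median of −0.03 and a test direction toward lower). Ptgs2, the inducible cyclooxygenase, rose by 0.73 ± 0.35 with both probes, while Ptgs1, the constitutive one, fell by 0.23 (SD 0.13). Ptgs1 read 1.03 with median centring and lost its call without replicate 2 (−0.27), 3 (−0.25) or 4 (−0.21), and Ptgs2 read 1.33 with the software's log ratio and lost its call without replicate 2, at 0.71. Alox5ap rose by 0.48 ± 0.20, but its call was lost in 4 of 21 alternatives, among them the software's log ratio (0.27), scale normalization (0.58) and the set without replicate 2 (0.45).

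In the JAK-STAT list 8 of 21 genes rose and 4 fell (Tyk2, Pim1, Stat3 and Stat2), 11 and 4 adjusted over the list alone (shift 0.02, adjusted p = 0.290). Of the 5 risen genes with more than 1 tested probe none (0) rose at every probe, and of 2 such fallen genes none (0) fell at every probe. This list passed as higher with no filter on dim probes (adjusted p = 0.0414) and with fry (0.0280). Tyk2 fell by 0.98 (SD 0.42, n = 4) but read −0.32 with median centring and lost its call. Pim1 read −0.66 and Jak2 0.60 at their brightest probes and 0.11 and −9.09e-04 at their other probes, and Pim1 did not pass without replicate 2 (−0.62) and read 0.042 with median centring. Interferon-stimulated genes were higher in 8 of 20 cases and lower in 3 (Irf7, Irf9 and Ddx58), as adjusted over the list alone (shift 0.06, adjusted p = 0.569, while fry called it higher at 0.0171), with Gbp3, a guanylate-binding protein gene, at 1.02 ± 0.16, Irf7 at −0.51 ± 0.41 and Irf9 at −0.32 ± 0.14, or 0.46 with median centring. Irf7 read −1.05 with the software's log ratio, and lost its call with median centring (−0.31) and without replicate 2 (−0.53) or 3 (−0.54), and Irf9 without replicate 2 (−0.32). Among 24 apoptosis and survival genes 8 rose and 4 fell (among them Bax, Bbc3 and Bad), 8 and 5 adjusted over the list alone (shift 0.02, adjusted p = 0.842). Here none (0) of the 5 risen genes with more than 1 tested probe rose at every probe, while 2 of 2 such fallen genes fell at every probe. Bcl2l11, which encodes the pro-apoptotic protein Bim, rose by 0.68 ± 0.06 at its brightest of 3 probes, of which the lowest read 0.15, and Trp53 by 0.45 ± 0.19, with its other probe at 0.12 and its call lost without replicate 2 (0.46). Of 27 cell cycle genes 4 rose (Cdkn1a, Pcna, Cdc20 and Mki67) and 4 fell (Top2a, Mcm2, Mcm6 and Mcm3), as adjusted over the list alone (adjusted p = 0.991, with a shift of 0.01 and a test direction toward lower). Cdkn1a, the cyclin-dependent kinase inhibitor p21, rose by 0.65 ± 0.17 and Pcna by 0.51 ± 0.12, and Top2a read −0.37 ± 0.25. Top2a read −0.88 with the software's log ratio, and lost its call with median centring (−0.24) and without replicate 2 (−0.37) or 3 (−0.38).

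Genes of the unfolded protein response and of glycolysis lay just short of the threshold as lists, with a lower test direction, and passed as lower in 10 and 6 of 23 alternatives. In the first, 8 of 21 measured genes fell and 3 rose (Canx, Ddit3 and Edem1), the same adjusted over the list alone, with a shift of −0.15 that turned to 0.41 with median centring (camera, adjusted p = 0.0503; adjusted p = 0.604 with an estimated correlation). Ppp1r15a, a phosphatase subunit that restores translation after stress, fell by 1.07 (SD 0.37, n = 4), Trib3 by 0.51 (SD 0.10) and Xbp1 by 0.50 (SD 0.14), while with median centring Trib3 and Xbp1 read 0.51 and 0.45 and Ppp1r15a, at −0.33, lost its call. In glycolysis and hypoxia 7 of 22 fell and 1 rose (Ldha), as adjusted over the list alone, with a shift of −0.14 that turned to 0.27 with median centring (adjusted p = 0.0537; adjusted p = 0.860 with an estimated correlation). Eno1, the glycolytic enolase, fell by 1.30 (SD 0.18), Tpi1 by 0.60 (SD 0.14) and Pkm by 0.60 (SD 0.33). A brighter probe under Pkm's older name, Pkm2, read −0.27 and did not pass (adjusted p = 0.0531 in limma). With median centring Tpi1 and Pkm read 0.62 and 0.31 and Eno1, at −0.50, lost its call, and Pkm did not pass without replicate 2 (−0.63).

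Sterol synthesis genes fell in 6 of 22 cases and rose in 4 (Idi1, Dhcr7, Nsdhl and Lss), 8 and 4 adjusted over the list alone (shift −0.09, and 0.23 with median centring; adjusted p = 0.318, while fry called it lower at 0.0192). All 4 risen genes had more than 1 tested probe, and none (0) rose at every probe. Of 4 such fallen genes 2 fell at every probe. Fdft1 read −0.47 ± 0.32 and Mvk −0.46 ± 0.26 (SD, n = 4), while with median centring Fdft1 read 0.29 and Mvk −0.0019. Without replicate 2 or 3 Fdft1 (−0.52 and −0.49) and Mvk (−0.45 and −0.44) did not pass. Adhesion and migration genes were higher in 5 of 25 cases (Itga5, Cxcr4, Icam1, Timp3 and Itgal) and lower in 7, or 6 and 8 adjusted over the list alone (shift −0.02, median 0.05, adjusted p = 0.842), with Adam17 at −0.61 ± 0.47, Itga5 at 0.52 ± 0.21 and Cxcr4 at 0.45 ± 0.17. Itga5 read 0.83 with the software's log ratio. Adam17 lost its call with median centring (−0.057) and without replicate 2 (−0.64) or 3 (−0.61). For oxidative stress and metal response, 3 of 20 rose (Fth1, Sod1 and Ftl1) and 3 fell (Keap1, Gclc and Gclm), as adjusted over the list alone (shift −0.02, adjusted p = 0.924), but the list passed as higher with median centring, at 0.45. Fth1, ferritin heavy chain, rose by 0.62 ± 0.13 but by 0.21 with the software's log ratio and 2.17 with median centring, Keap1 read −0.57 ± 0.15 and Gclc −0.50 ± 0.15, and with median centring these 2 read 0.39 and 0.50. Housekeeping genes were not level: of 15 measured, 4 were higher (Rpl13a, B2m, Hprt and Rplp0) and 7 lower, 5 and 7 adjusted over the list alone (shift −0.10, turning to 0.54 with median centring; adjusted p = 0.290). Actb, the β-actin gene, fell by 0.59 (SD 0.08) at both probes and read 0.62 with median centring. Ywhaz fell by 1.03 (SD 0.19) at its brightest probe and read −0.01 at the other, and −0.022 with median centring. Rpl13a rose by 0.68 ± 0.10, or 0.45 with the software's log ratio.

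Markers of other cell types were measured beside these groups. The 4 measured eosinophil markers passed as a list (shift 0.34, camera, adjusted p = 0.0308; adjusted p = 0.604 with an estimated correlation), with 2 higher and none (0) lower, as adjusted over the list alone. They were the eosinophil ribonuclease genes Ear1, at 0.72 ± 0.16, and Ear6, at 0.67 ± 0.14 (SD, n = 4), while Ccr3 and Siglecf read 0.08 and −0.05. This call was lost in 9 of 23 alternatives, among them the software's log ratio (adjusted p = 0.0828), scale normalization (0.137) and the set without replicate 4 (0.0571), and its adjusted p over all alternatives ranged from 0.00986 to 0.604. Of 11 macrophage markers 2 were higher, Adgre1 at 0.28 ± 0.17 and Mpeg1 at 0.15 ± 0.06, and none (0) adjusted over the list alone (shift 0.01, adjusted p = 0.991). Mpeg1 lost its call in 11 of 21 alternatives, among them without replicate 1 (0.13), 2 (0.18), 3 (0.14) or 4 (0.14), and Adgre1 in 5, among them without replicate 2 (0.30) or 3 (0.33). Of 8 neutrophil markers 1 was higher, Mmp8 at 0.28 ± 0.12, also adjusted over the list alone (adjusted p = 0.991), but not without replicate 2 (0.25) or 3 (0.25), and it read 0.51 with the software's log ratio. In the list drawn up in advance as basophil markers 3 of 9 were higher (Mcpt8 at 0.41 ± 0.09, Gata2 and Cd200r3). Another 2 were lower (Itga2b at −1.78 ± 0.31 and Cebpa at −0.51 ± 0.35), and the counts adjusted over the list alone were the same. Whether Itga2b and the other members are specific to basophils was not tested. The list had a median of 0.12, a shift of −0.12 and a test direction toward higher (adjusted p = 0.991). Cebpa read −0.12 at its other probe, without a call, and −1.04 with the software's log ratio. It lost its call with median centring (−0.29) and without replicate 2 (−0.54) or 3 (−0.51).

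The lists of the remaining cell types did not pass with camera, while fry called the erythroid and megakaryocyte list higher (adjusted p = 0.0179). Dendritic cell and MHC class II markers had 2 of 11 higher (Xcr1 at 0.43 ± 0.30 and Clec10a at 0.22 ± 0.13; SD, n = 4) and 1 lower, Itgax, at −0.21 ± 0.07 with its other probe at 0.30, as adjusted over the list alone (adjusted p = 0.991). Lymphocyte and NK markers had 2 of 13 higher (Ncr1 at 0.17 ± 0.07 and Il7r at 0.15 ± 0.08) and 1 lower, Cd8b1, at −0.48 ± 0.25 with its other probe at 0.09, or 1 and 1 adjusted over the list alone (adjusted p = 0.991). In the erythroid and megakaryocyte list 1 of 11 was higher, Tfrc at 0.28 ± 0.24 on 3 of 4 arrays, and none (0) adjusted over the list alone (adjusted p = 0.924). Of 8 fibroblast and stroma markers 1 was higher, Thy1 at 0.31 ± 0.18, and 1 lower, Acta2 at −0.32 ± 0.19 with its other probe at 0.05, as adjusted over the list alone (adjusted p = 0.842). Several of these calls were lost when 1 array was left out. Without replicate 2 or 3 the calls of Xcr1 (0.43 and 0.41), Clec10a (0.25 and 0.24), Itgax (−0.21 and −0.22), Ncr1 (0.14 and 0.17), Il7r (0.18 and 0.17), Tfrc (0.26 and 0.26), Acta2 (−0.33 and −0.35) and Thy1 (0.33 and 0.26) were lost, and that of Cd8b1 without replicate 2 (−0.49). Without replicate 1 Clec10a (0.21), Il7r (0.16) and Tfrc (0.22) did not pass, nor did Clec10a (0.16) and Il7r (0.11) without replicate 4. With median centring Itgax, Cd8b1 and Acta2 read 0.59, 0.11 and 0.93, and with the software's log ratio Clec10a, Ncr1 and Thy1 read 0.35, 0.39 and 0.70. Across the 28 lists, 6 passed as higher and none (0) as lower, while the count with an estimated correlation was 0, and fry, which asks whether a list moves one way on balance, called 11 higher and 2 lower.

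**Figure D4:**
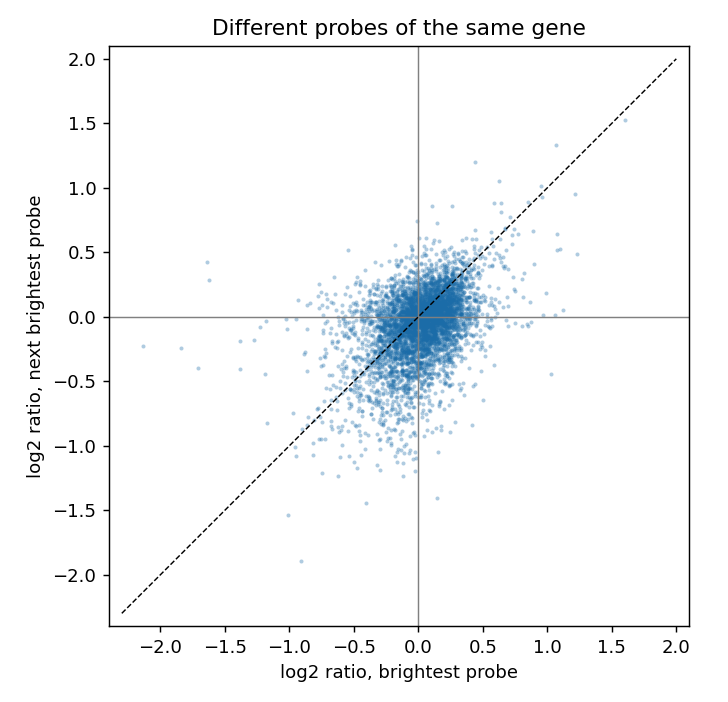
Log2 ratios of the brightest probe (horizontal axis) and the next brightest probe (vertical axis) of 5223 genes with more than 1 tested probe, 1 point per gene, mean of 4 arrays; the dashed line marks equal values. Pearson's r across genes was 0.429, and the 5 genes with the largest falls at the brightest probe read between −0.40 and 0.43 at the next.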

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

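The counts over sign patterns of the arrays were planned before the data were examined; the tests on different probes of 1 gene and on lists drawn from genes of like brightness were chosen after the results were seen.

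Among the 94 named genes 4 had 1 array far from the other 3. Nfkbiz read 1.88 on the array of replicate 3, above the others. Rpl12 (1.11), Cd63 (0.70) and Fas (0.71) were lowest on the array of replicate 1. Chance alone gives about 4.7 such genes among 94. Over all 16930 genes with 4 values 978 (5.78%) had such an array, with replicate 4 named for 528 of them and replicate 1 for 299. The scanner software's correlation of measured with nominal spike-in ratios was 0.964 on the array of replicate 4, apart from the other 3.

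The first pattern is that 33.4% of the tested genes passed the threshold. Of the 8 sign patterns of the 4 arrays 1, the real one, gave as many genes (5666, against 0 for the highest other), but 8 patterns are too few for a share under 0.05. Over the 5223 genes with more than 1 tested probe, the brightest probes of a gene correlated with r = 0.429 (95% interval 0.400 to 0.458), while the average of 2 arrays correlated with that of the other 2 with r from 0.836 to 0.903 over the same probes, and of 2111 genes called at their brightest probe 38.1% had the same call at the next. Dim probes, whose ratios the offset pulls toward 0, may account for part of this: with both probes at or above the median intensity (2025 genes) r was 0.507 (0.461 to 0.548) and 53.2% of 909 called genes had the same call. This is consistent with effects of single probes, such as dye bias or cross-hybridization, that repeat on every array and may add to the calls. For genes that fell at least 2-fold the other probes had a median of −0.19 (−0.41 to −0.03, 15 genes). For 7 of these the other probes were dim, with a median of −0.23 (−0.41 to −0.08) against −1.23 at their brightest probes. How much of this gap the offset makes was not tested. The 8 genes with bright other probes had a median of −0.19 too (−0.44 to 0.29), against −1.33 at their brightest probes. For genes that rose at least 2-fold the other probes had a median of 0.52 (0.05 to 0.98, 10 genes), which leaves that explanation undecided for the rises. Without an exchange of dyes these effects and an effect of IL-18 itself both stay open, as do effects of base composition and transcript length, which were not tested.

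The second pattern is the rise of ribosomal protein genes, of which 68 of 80 were called higher. Their median of 0.56 exceeded 100% of 10000 random lists matched on brightness (median 0.18), and the highest of these reached 0.32, which argues against brightness alone as the source, although such lists ignore correlation between genes and the family was chosen because it read high. The other probes of 41 of these genes had a median of 0.27 (0.08 to 0.41), against 0.56 at the brightest probes. That interval lies above 0 but holds 0.18, the median of the lists matched on brightness. It therefore cannot decide on effects of single probes. Bright other probes (33 genes) had a median of 0.38 (0.24 to 0.49), an interval above 0.18. Dim other probes (11 genes) had a median of 0.02 (−0.07 to 0.08), against 0.35 at the brightest probes of the same genes. How much the offset lowers these was not tested. A dye effect shared by transcripts of this class, for instance through their short length, may remain, and was not tested, and so does an effect of IL-18.

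The third pattern is that 6 gene lists passed as higher, among them those of NF-kB, chemokine, cytokine and immediate-early genes. With a correlation between genes estimated from the arrays 0 passed (adjusted p = 0.604 for each of the 6). That test cannot tell whether correlation undoes the calls, since 4 arrays leave it few degrees of freedom. The costimulatory and eosinophil lists had estimated correlations of −0.025 and 0.0031, below the preset 0.01. Their unadjusted camera p-values still rose from 9.06e-04 and 0.0066 to 0.084 and 0.173. Estimates for the 4 lists named above were higher, from 0.143 to 0.285. Of the 8 sign patterns 2 gave as many lists (6 in the real one, 7 in the highest other, which sets replicates 1 and 4 against 2 and 3 and so does not follow the slides), and 8 are too few for a share under 0.05. All 28 lists were drawn anew 10000 times from genes of like brightness, so that no list had to be picked for the draws. The rank compared, the fourth largest, was set after the results were seen, to match the number of lists named. The fourth largest list median, that of the 4 eosinophil markers, whose call is lost in 9 of 23 alternatives, lay 3.83 SD above its draws and above 100% of the fourth largest of the draws (highest 2.30). Of the 4 lists named, NF-kB (8.12), chemokines (5.67) and cytokines (4.79) had the 3 largest values and immediate-early genes the sixth (3.47, above 99.2% of the largest of the draws). This argues against dye effects of single probes unrelated to the genes' function as the whole cause, although the draws ignore correlation between genes. For the 25 members of the 4 lists with more than 1 probe the brightest probes had a median of 0.25 and the other probes one of 0.079 (−0.16 to 0.23). Of 15 called higher at the brightest probe, 7 were called higher at every other probe and 3 were called lower at another. Bright other probes (10 genes) had a median of −0.17 (−0.31 to 0.35), against 0.14 at the brightest probes of the same genes, which leaves effects of single probes open for these, and the other 63 members have 1 tested probe. With the probe nearest to 0 of each gene 5 of the 6 lists kept their call. An effect of IL-18, the explanation the design gives, stays open as a hypothesis.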

How the results depend on the processing

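Settings chosen after the data were examined were the probe nearest to 0 for each gene, calls on all of at least 2 probes, and the arrays of 1 slide alone.

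Against 3346 genes higher and 2320 lower, median centring in place of loess gave 10701 and 77, and 805 genes called lower became higher; its median log2 ratio of 0.43 against 0.02 shows that a trend with brightness was left in, whose source was not tested. Stricter rules gave fewer calls by construction: 1289 and 750 at an adjusted p under 0.01, 33 and 55 at 2-fold, 289 and 360 with all of at least 2 probes past the threshold. Slide 1 alone gave 1806 and 1207 and slide 2 alone 1573 and 1704, with fewer arrays. Leaving out 1 replicate gave 1039 to 3534 higher and 569 to 3000 lower, lowest without replicate 2 (1039 and 569) and replicate 3 (1275 and 804). The scanner software's log ratio gave 4863 and 2931, the values of the series table gave 4863 and 2929, no background subtraction 4796 and 3408, and separate channels 2598 and 2058. Leaving out saturated spots removed nothing and so tested nothing.

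Of the gene lists 6 were higher and 0 lower. With an estimated correlation 0 were higher, and with fry 11 were higher and 2 lower. Lists called lower numbered 2 with the probe nearest to 0, a normexp offset of 0 or no filter on dim probes, and 1 with the software's log ratio, the series table, both channels above background or slide 1 alone. Leaving out 1 replicate gave 5 to 6 higher and 0 to 2 lower. Median centring gave 9 higher. The unfolded protein response list passed as lower in 10 of 23 settings and the glycolysis list in 6. For these the cause was not tested.

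Among results past the threshold in the setting reported or in the alternative, signs reversed as follows, and the cause was not tested. Oxidative stress and metal response read 0.45 with median centring. With the same setting Map2k3 read 0.50, Tpsb2 0.47, Csf2rb 0.078, Ptgs1 1.03, Pim1 0.042, Irf9 0.46, Trib3 0.51, Xbp1 0.45, Tpi1 0.62, Pkm 0.31, Fdft1 0.29, Keap1 0.39, Gclc 0.50, Actb 0.62, Itgax 0.59, Cd8b1 0.11 and Acta2 0.93. At the probe nearest to 0 Cox17 read 0.43, Klf2 0.29, Pim1 0.11, Jak2 −9.09e-04, Cd8b1 0.092 and Acta2 0.047. Itgax read 0.043 as the median of its probes. Il1rl1 read −0.082 with the software's log ratio and −0.082 with the series table. Results past the threshold in neither changed sign too: 22 lists in 66 cases, and Mcpt2 and Kit in 5. With median centring the unfolded protein response read 0.41, glycolysis 0.27, sterol synthesis 0.23 and housekeeping genes 0.54. With the software's log ratio the mast cell lists read −0.036 and −0.042, Mcpt2 −0.14 and Kit −0.12.

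Of the 94 named genes 31 lost their call without replicate 2, 23 without replicate 3, and 13 with separate channels. With median centring 15 lost it and another 17 reversed in sign, and Mcpt2 and Kit gained a call. Between 49.9% and 62.7% of gene spots stood well above background in a channel, which limits what can be said of weakly expressed genes.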

Other observations

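Families of genes grouped by symbol were chosen after the data were seen, 14 in all, of whose 377 members 12 also belong to the 28 lists, and tested with camera with adjustment over the 14. With an estimated correlation, for which 4 arrays leave few degrees of freedom, none (0) passed. The 6 families past the threshold with the preset correlation had an adjusted p of 0.474 each in that test. Ribosomal protein genes had 68 of 80 higher and 2 lower, with a median log2 ratio of 0.56 (0.32 with the software's log ratio and 2.00 with median centring; adjusted p = 1.16e-44, or 0.474 with an estimated correlation) that was above 0 on 4 of 4 arrays. Subunits of mitochondrial complex I had 19 of 36 higher and 2 lower (median 0.18, or 1.35 with median centring, adjusted p = 5.91e-05), and histone genes 28 of 46 higher and 5 lower (median 0.20, or 0.99 with median centring, adjusted p = 8.33e-07), and both had an adjusted p of 0.474 with an estimated correlation. Among the families, random lists matched on brightness were drawn for ribosomal protein genes alone, with a median of 0.18. Whether brightness accounts for the values of the other families was not tested. In the Gadd45 and Btg family of growth arrest genes 4 of 6 were higher (Btg2 at 1.23, Gadd45b at 1.07, Btg1 at 0.55 and Btg3 at 0.18) and 0 lower (median 0.36, or 1.58 with median centring, adjusted p = 1.75e-04, or 0.474 with an estimated correlation).

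Cytosolic aminoacyl-tRNA synthetase genes had 13 of 20 lower and 1 higher (Farsa), with a median of −0.34 that turned to 0.70 with median centring (adjusted p = 2.50e-05). Subunits of the chaperonin had 4 of 10 lower (Cct3, Cct4, Cct6a and Cct7) and 1 higher (Cct5), with a median of −0.15 that turned to 0.84 with median centring (adjusted p = 0.0192). Both medians were below 0 on 4 of 4 arrays, and both families had an adjusted p of 0.474 with an estimated correlation. The other 8 families did not pass, among them cytochrome c oxidase subunits (adjusted p = 0.0643), cathepsins (adjusted p = 0.185) and proteasome subunits (adjusted p = 0.749).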
